A study of Rattus norvegicus with 12 samples.

How the data were processed

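Poly(A) RNA sequencing was done on NRK-49F cells, a fibroblast line from rat kidney. The cells had been transfected with an empty vector or with a plasmid for human HDAC1 carrying a Flag tag, and were then kept for 24 hours in low-serum medium without (vehicle) or with 2 ng/ml of the cytokine TGFB1. Per the labels' titles, the 12 libraries form 4 groups of 3: empty vector with vehicle, HDAC1 with vehicle, empty vector with TGFB1 and HDAC1 with TGFB1. The titles were used for the groups because the treatment field of the labels runs as a numbered series of names instead of giving the dose, and because the design text describes all cells as treated. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between libraries.

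The authors deposited a table of raw counts per gene and a second table of normalized counts. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, counted with featureCounts (Subread 2.0.1) and analysed with DESeq2 1.44. These notes name the mouse build mm10, whereas the gene identifiers in both tables are those of rat Ensembl genes. The aligner, the rat build and the handling of reads that fit more than 1 gene are not stated, so no coordinates are given and genes with near-identical copies are uncertain. The values of the deposited normalized signal were checked against the deposited counts: each of its columns is the raw count column divided by 1 constant per library, and it keeps the 14275 genes with a total of at least 100 counts. Gene symbols came from that table and from a RefSeq gene table of the assembly GRCr8, used for names and for neighbouring genes only. Of the genes tested, 1909 had no symbol and 155 shared a symbol with another gene.

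Raw counts of 43360 genes were used for all tests, and 13039 of these genes had 0 counts in every library. Library totals ran from 18397093 to 36652084 counts. Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 14601 genes holding at least 99.879% of each library's counts, and libraries were scaled with TMM. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to the 12 libraries together, which left 8 residual degrees of freedom. The common biological coefficient of variation was 7.61%. The contrasts were the effect of HDAC1 in vehicle and with TGFB1, the effect of TGFB1 with the empty vector and with HDAC1, the difference between the effects (the interaction), and the average effect of each factor. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Expression levels are CPM (counts divided by the library total of the tested genes after TMM scaling, on the usual scale of cpm in edgeR). They are given as the mean and SD of 3 libraries.

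Before the data were examined, 27 gene lists were fixed (matrix and collagen genes, contractile genes, TGF-beta and YAP/TAZ targets, proteases, HDAC family and complexes, acetyltransferases, cell cycle, p53 targets, interferon and NF-kB targets, stress responses, metabolism, ribosomal proteins and cell type markers). They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and adjusted over all lists and the 5 contrasts. The tests were repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. For each list, members were counted as called over all genes and as called when adjusted over the list alone.

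The rule for the named genes was also fixed before the data were examined. It takes Hdac1 and 8 genes of fibrosis, TGF-beta signalling and cell cycle arrest in every comparison, and the 10 largest rises and falls per comparison among called genes with a symbol, a mean log2 CPM of at least 2 and all 3 libraries of one group beyond all 3 of the other. For the interaction it takes the 5 largest each way, and for each list and comparison up to 4 members with the smallest adjusted p. Genes named outside this rule are said to be so.

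The same steps were tested on simulated data with 200 changed genes among 14601 genes at the measured means and library sizes. For the HDAC1 effect in vehicle, 71% of the genes changed by 1.5-fold, 78% of those changed by 2-fold and 95.5% of those changed by 4-fold were recovered. For the interaction these shares were 46%, 74.5% and 88.5%. A list raised by 1.3-fold was called and 0 others were. The simulated genes were drawn independently, so this check does not show how often lists of correlated genes are called by chance.

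Alternatives were DESeq2 size factors, the test of DESeq2 1.42.0, no filter on low counts, a mean CPM of at least 1, a fit to the 2 groups compared, a replicate block, and leaving out each library in turn. After the data were seen, 3 more were added: a covariate for transcripts of heart and brain, leaving out the genes low in replicate 1 of the empty vector vehicle group, and a correlation of DESeq2 fold changes over the genes tested here. The covariate was the log2 of the summed CPM of 21 heart and 20 brain genes. Those lists, and lists of liver, skin and kidney tubule genes, were written after the data were seen. A gene was taken as low in that replicate where its CPM was at most 0.5 times the mean of replicates 2 and 3, which held for 792 tested genes. No check of GC content or gene length was made, because no genome of the build used for counting was available.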

Results

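Expression of 14601 genes was measured by RNA sequencing in 12 libraries of rat kidney fibroblasts of the line NRK-49F. The groups combined an empty vector or a human HDAC1 plasmid with vehicle or TGFB1, a cytokine that turns fibroblasts into matrix-producing myofibroblasts, with 3 libraries per group. HDAC1 is a histone deacetylase, an enzyme that removes acetyl groups from histones. Library totals were 18397093 to 27119357 counts for the empty vector with vehicle and 24662270 to 36652084 for HDAC1 with vehicle. With TGFB1 they were 20844186 to 23619883 for the empty vector and 18661922 to 26570112 for HDAC1. The first principal component held 54.74% of the variance and separated the vehicle libraries from the TGFB1 libraries, and the second held 14.14%. The third held 8.236%, and on it all HDAC1 libraries (-1.073 to 27.85) lay above all empty vector libraries (-26.75 to -2.029). The second did not separate HDAC1 from the empty vector over both treatments. On it, replicate 1 of the empty vector vehicle group (37.6) and the libraries with HDAC1 and TGFB1 (16.4 to 24.58) lay apart from all others (-28.57 to -0.0042). These libraries also had the lowest levels of heart and brain transcripts, described below.

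Hdac1 (ENSRNOG00000009568) was measured first, as a check of the labels. It was at 210 ± 4.13 CPM (SD, n = 3) with the empty vector and 421 ± 43.3 CPM with the plasmid in vehicle, a 2.01-fold rise (edgeR adjusted p = 9.29e-07). With TGFB1 it was at 267 ± 21.1 CPM and 464 ± 43.5 CPM, a 1.74-fold rise (edgeR adjusted p = 1.60e-05). A far larger rise was seen in Hdac1l (ENSRNOG00000013695), a rat gene named as a copy of Hdac1, from 8.29 ± 7.33 to 1172 ± 279 CPM in vehicle and from 9.30 ± 1.64 to 1090 ± 251 CPM with TGFB1 (edgeR adjusted p = 0.000238 and 0.00122). For each gene and treatment, all 3 HDAC1 libraries lay above all 3 empty vector libraries, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The plasmid carries the human sequence, and the counts do not show how its reads were divided between the 2 rat genes, so both values are uncertain as levels of the rat transcripts. Their sum was 7.31-fold higher with the plasmid in vehicle and 5.63-fold higher with TGFB1.

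**Figure D1:**
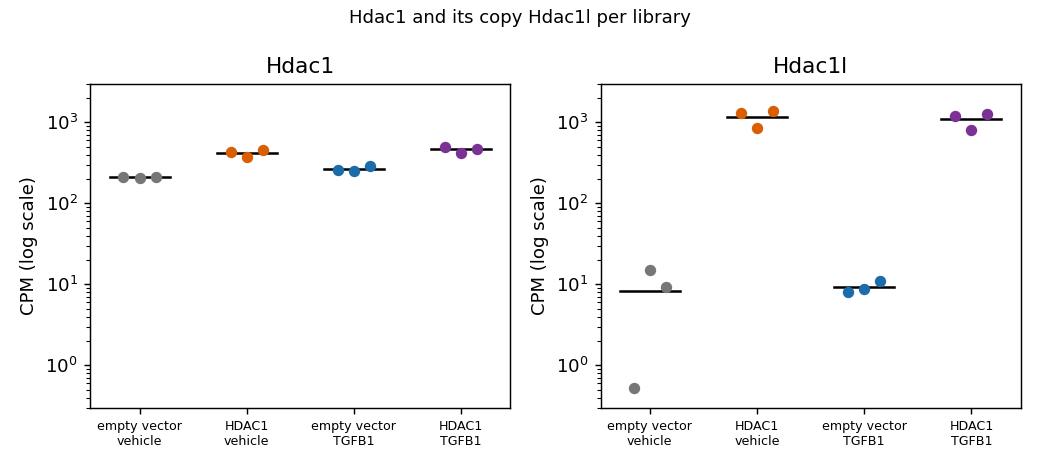
CPM of Hdac1 and Hdac1l in each library on a log axis, with points for the 3 libraries of each group and a line at the group mean. Hdac1l rose from 8.29 to 1172 CPM in vehicle and from 9.30 to 1090 CPM with TGFB1.

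Which genes HDAC1 changed without added cytokine was asked first. Cell division genes rose together: all 30 tested members of the mitosis list were higher, with a median log2 fold change of 0.54. Examples were Kif20a, a motor of cell division, which went from 85.4 ± 5.48 to 143 ± 7.77 CPM, Ccnb1 (cyclin B1), which rose by 0.70 on the log2 scale, and Cdc20, which rose by 0.76. Of the 30 DNA replication genes, 24 rose and 6 were not called (27 rose when adjusted over the list alone), among them Rrm2, a subunit of ribonucleotide reductase (0.64), and E2f1 (0.55). The camera test gave adjusted p = 1.72e-30 for mitosis and 8.10e-20 for replication, and adjusted p = 0.294 for both with an estimated correlation. Cdkn1b, an inhibitor of cell cycle kinases, fell (log2 fold change -0.45), while Cdkn1a was at 182.2 ± 12.3 and 190.5 ± 3.66 CPM (log2 fold change 0.06, edgeR adjusted p = 0.576).

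Interferon-stimulated genes were lower with HDAC1 in vehicle. Of 37 tested, 24 fell, 1 rose and 12 were not called (30 fell and 1 rose when adjusted over the list alone). Irf7, a transcription factor of the interferon response, fell from 2832 ± 76.4 to 1739 ± 185 CPM, the antiviral gene Oas2 fell by 0.81 and Bst2 fell by 0.75 on the log2 scale. The gene that rose was Ifit3 (0.47). The list had a median log2 fold change of -0.27 (camera adjusted p = 5.93e-13, and adjusted p = 0.523 with an estimated correlation). Guanylate-binding protein gene Gbp1, also induced by interferon, was among the 10 largest falls (-1.18).

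Part of the matrix genes also fell in vehicle. Of 19 collagens, 8 fell, 2 rose and 9 were not called (10 and 2 called when adjusted over the list alone). Col1a1, the main chain of type I collagen, went from 5200 ± 502 to 3375 ± 559 CPM (log2 fold change -0.62 ± 0.14 SE, edgeR adjusted p = 0.00946), Col1a2 fell by 0.54 and the basement membrane chain Col4a1 fell by 0.41. Among 20 collagen processing genes, 13 fell and 0 rose (16 fell when adjusted over the list alone), with Loxl3, a crosslinking enzyme, at -0.57 and P3h3, a prolyl hydroxylase, at -0.57. Among 27 matrix glycoproteins, 8 fell and 0 rose (9 fell when adjusted over the list alone), including Sparc (-0.76), Fbln5 (-0.66) and Aspn (-1.09). The camera adjusted p was 0.00442 for collagens, 2.69e-07 for processing and 0.00144 for glycoproteins, against adjusted p = 0.634, 0.587 and 0.527 with an estimated correlation.

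The TGF-beta signalling list was slightly lower in vehicle, with 6 of 29 genes down and 0 up, the same numbers when adjusted over the list alone. They included the ligand genes Tgfb2 (-0.69) and Tgfb3 (-0.34). The median was -0.11 (camera adjusted p = 0.00123, and adjusted p = 0.527 with an estimated correlation). Ccn2, a TGF-beta target with a role in scarring, fell from 288 ± 47.8 to 189 ± 11.3 CPM (log2 fold change -0.61, edgeR adjusted p = 0.00104). Of the other fibrosis genes, Acta2 (smooth muscle actin) had a log2 fold change of -0.26 (edgeR adjusted p = 0.290), Col3a1 of -0.22 (0.553), Fn1 of -0.22 (0.166) and Tgfb1 of -0.11 (0.355), and none of them was called. The list of proteases and inhibitors had 9 genes down and 2 up of 27 (12 and 4 when adjusted over the list alone), with the matrix protease Mmp2 at -0.48, a median of -0.18 and camera adjusted p = 0.00480 (adjusted p = 0.294 with an estimated correlation).

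Other groups rose with HDAC1 in vehicle. Of 24 cholesterol synthesis genes, 10 rose and 0 fell (14 rose when adjusted over the list alone), with Acat2 at 0.57 and Msmo1 at 0.42 (camera adjusted p = 1.35e-05, and adjusted p = 0.610 with an estimated correlation). Of 13 genes encoded in the mitochondrial genome, 10 rose, also when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 3.44e-06, and adjusted p = 0.527 with an estimated correlation). They took 1.81 ± 0.0534% of the counts with the empty vector and 2.23 ± 0.180% with HDAC1. Among the 10 largest rises besides Hdac1l were Cxcl2, a chemokine for neutrophils, from 2.52 ± 0.362 to 6.72 ± 1.16 CPM, Tmcc3, from 1.91 ± 0.178 to 4.98 ± 0.694 CPM, Krt79 (1.27), Il1rl1, the receptor of interleukin 33 (1.23), Ngfr (1.20) and the growth factor Csf2 (1.12). Among the 10 largest falls were the chemokine Cxcl13, from 16.1 ± 2.91 to 6.14 ± 0.644 CPM, Ccn3 (-1.33), Mpeg1 (-1.29), Lbp (-1.27), Ccn5 (-1.22) and the cholesterol exporter Abca1 (-1.15).

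In all, edgeR called 2038 genes in vehicle, 969 higher and 1069 lower with HDAC1, of which 117 changed by at least 2-fold (78 higher and 39 lower). The count was 1239 without replicate 1 of the empty vector vehicle group and 1144 without replicate 1 of the HDAC1 vehicle group. The calls of 3 lists with small medians ended without single libraries: oxidative phosphorylation (median 0.06) was not called without HDAC1 vehicle replicate 2 (0.04), glycolysis (0.05) without empty vector vehicle replicate 2 (0.09) or HDAC1 vehicle replicate 2 (0.04), and immediate early and heat shock genes (0.15) without empty vector vehicle replicate 2 (0.15) or HDAC1 vehicle replicate 1 (0.03). The neuronal list (median 0.27) turned to -0.16 without replicate 1 of the empty vector vehicle group, in which 20 of its 25 genes were low. The 4 lists had 3, 5, 6 and 1 genes up, also when adjusted over the list alone, and camera adjusted p = 0.0158, 0.0232, 0.0397 and 0.00880, against adjusted p = 0.757, 0.610, 0.712 and 0.757 with an estimated correlation. By fry, 5 lists called by camera did not pass: collagens (fry adjusted p = 0.0989), cholesterol synthesis (0.0887), immediate early and heat shock genes (0.217), neuronal genes (0.291) and oxidative phosphorylation (0.290). The other 13 lists were not called (camera adjusted p from 0.0702 to 0.960), and they included the HDAC family, HDAC1 complex subunits and acetyltransferases.

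HDAC1 was next compared with the empty vector in cells given TGFB1. Interferon-stimulated genes were again lower, with 20 of 37 down, 1 up and 16 not called (22 and 2 when adjusted over the list alone). Irf7 fell from 2045 ± 188 to 1185 ± 126 CPM, Gbp4 fell by 0.76 and Isg20 fell by 0.72 on the log2 scale, and Ifit3 rose by 0.52. The list median was -0.27 (camera adjusted p = 3.78e-08, and adjusted p = 0.527 with an estimated correlation). Zbp1, an interferon-induced sensor of nucleic acid, fell from 17.6 ± 2.79 to 6.52 ± 1.17 CPM. Ifnb1, the gene of interferon beta itself, rose from 5.52 ± 0.806 to 12.5 ± 1.36 CPM.

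Some inflammatory genes and the matrix proteases Mmp13 and Mmp3 rose with HDAC1 in the presence of TGFB1. Of 28 NF-kB targets, 7 rose, 0 fell and 21 were not called (11 rose and 2 fell when adjusted over the list alone), with Csf2 at 1.01, Tnfaip3, a brake on NF-kB, at 0.77 and Tnf at 0.80 (camera adjusted p = 0.00243, and adjusted p = 0.587 with an estimated correlation). The collagenase Mmp13 rose from 10.4 ± 2.63 to 30.6 ± 6.48 CPM (log2 fold change 1.54 ± 0.15 SE, edgeR adjusted p = 5.31e-05), and the stromelysin Mmp3 rose from 61.5 ± 7.97 to 174 ± 41.0 CPM. The list of proteases and their inhibitors was not called as a whole, with 3 up and 1 down of 27 (4 and 4 when adjusted over the list alone, camera adjusted p = 0.964). Plk2, a kinase induced by stress, rose by 0.70. Genes of the mitochondrial genome were higher in 8 of 13 cases (12 when adjusted over the list alone), with Mt-cyb at 0.64 and a list median of 0.37 (camera adjusted p = 2.76e-10, and adjusted p = 0.523 with an estimated correlation). Their share of the counts was 1.83 ± 0.0230% with the empty vector and 2.26 ± 0.155% with HDAC1.

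Some matrix genes were lower with HDAC1 and TGFB1 together than with TGFB1 alone. Of 20 collagen processing genes, 6 fell and 0 rose (15 fell when adjusted over the list alone), with Loxl3 at -0.69, Adamts2 at -0.49 and P3h3 at -0.49 (camera adjusted p = 6.86e-07, and adjusted p = 0.587 with an estimated correlation). Of 27 matrix glycoproteins, 3 fell and 0 rose (5 fell when adjusted over the list alone), including Sparc, from 1125 ± 212 to 670 ± 62.1 CPM, and Fbln5 (-0.44), with camera adjusted p = 0.000158 and adjusted p = 0.527 with an estimated correlation. Of 19 collagens, 3 fell (4 when adjusted over the list alone), with a median of -0.15 and camera adjusted p = 0.0176 (adjusted p = 0.712 with an estimated correlation). The collagen call ended without empty vector TGFB1 replicate 1 (median -0.07) or HDAC1 TGFB1 replicate 1 (-0.09). Ccn2 fell from 1150 ± 147 to 707 ± 30.7 CPM (log2 fold change -0.70, edgeR adjusted p = 0.00123). Col1a1 had a log2 fold change of -0.47 (edgeR adjusted p = 0.0644), Tgfb1 of -0.23 (0.0560), Col3a1 of -0.36 (0.329) and Fn1 of -0.02 (0.917), and none of these was called. Without HDAC1 TGFB1 replicate 2, Col1a1 (-0.60) and Tgfb1 (-0.29) were called. With a covariate for heart and brain transcripts, 63 of the 86 calls of named genes in this comparison ended. Among them were Sparc, Adamts2, P3h3 and Tnf, at log2 fold changes of -0.75, -0.51, -0.50 and 0.77.

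Acta2 went from 21.4 ± 3.67 to 16.0 ± 0.785 CPM with TGFB1 (log2 fold change -0.41 ± 0.11 SE, edgeR adjusted p = 0.0331). This call ended in 5 of the 6 fits without 1 library of the comparison, with -0.42 and -0.29 without empty vector TGFB1 replicates 1 and 3 and with -0.39, -0.46 and -0.41 without HDAC1 TGFB1 replicates 1, 2 and 3. It also ended with the covariate (-0.32, edgeR adjusted p = 0.502). Of 22 contractile genes, 5 fell and 1 rose (11 and 1 when adjusted over the list alone), with camera adjusted p = 0.000380 and adjusted p = 0.294 with an estimated correlation. Of those 5 genes, 2 were low in replicate 1 of the empty vector vehicle group, as were all 21 heart genes and all 20 brain genes measured. Aqp1, a water channel, fell by 0.91.

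**Figure D2:**
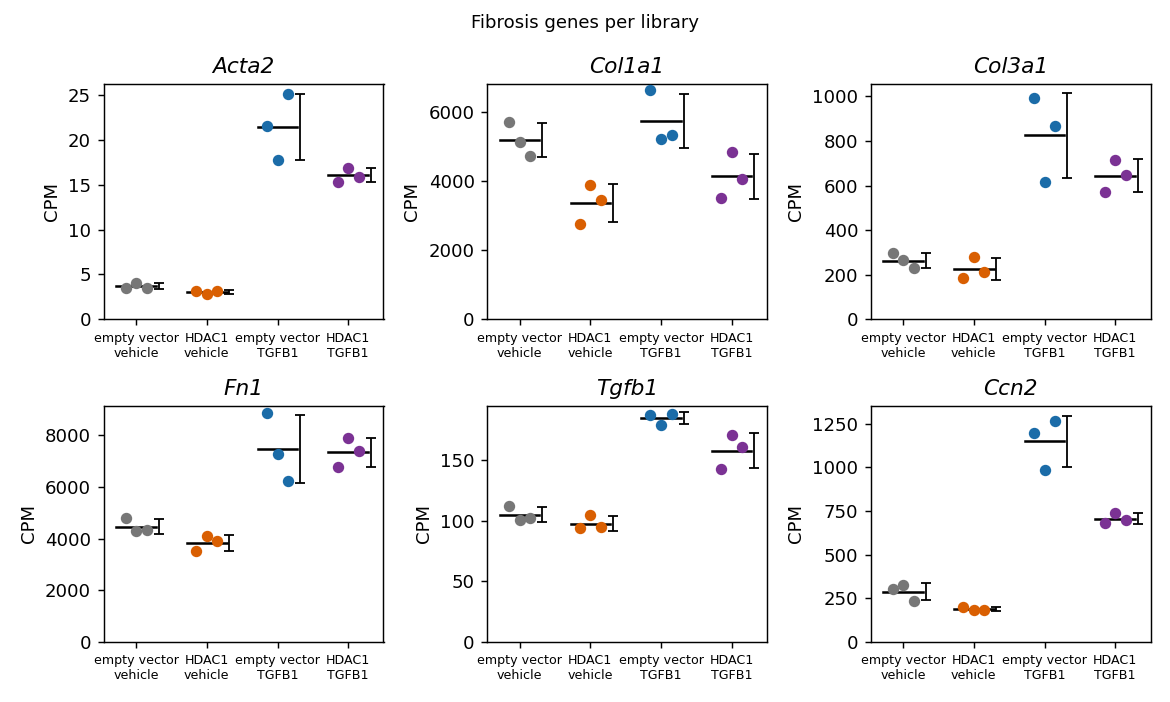
CPM of 6 fibrosis genes per library, with points for libraries, a line at the mean of the 3 libraries of each group and bars of 1 SD. Acta2 was at 21.4 CPM with TGFB1 and the empty vector and 16.0 CPM with TGFB1 and HDAC1, and Ccn2 at 1150 and 707 CPM.

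Cell cycle genes were less altered by HDAC1 when TGFB1 was present. Of 30 mitosis genes, 9 rose (16 when adjusted over the list alone) with a median of 0.18 (camera adjusted p = 2.98e-09, and adjusted p = 0.527 with an estimated correlation). Of 30 replication genes, 3 rose (5 when adjusted over the list alone) with a median of 0.11 (camera adjusted p = 0.000937, and adjusted p = 0.610 with an estimated correlation).

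Transcripts of heart and brain, chosen after the values were seen, were measured in every library of these kidney fibroblasts. The 21 heart genes summed to 70.9 CPM in replicate 1 of the empty vector vehicle group, to 404.7 and 432 CPM in replicates 2 and 3, and to between 153.6 and 173.2 CPM in the 3 libraries with HDAC1 and TGFB1. In the libraries with TGFB1 and the empty vector they summed to between 458.4 and 581.6 CPM. The 20 brain genes moved alongside, from 17.89 CPM in that replicate to between 44.97 and 49.54 CPM with HDAC1 and TGFB1. The neuronal list was the most altered in this comparison (median -1.46, 7 of 25 genes down, 18 down and 1 up when adjusted over the list alone), and all 7 genes were low in that replicate (camera adjusted p = 5.26e-06, and adjusted p = 0.610 with an estimated correlation). The endothelial list also fell, with 2 of 11 genes down (6 when adjusted over the list alone), a median of -0.47 and camera adjusted p = 0.00625 (adjusted p = 0.294 with an estimated correlation), and 3 of its 11 genes were low in that replicate. Median log2 fold changes were -1.59 for heart genes (1 of 21 called lower) and -1.62 for brain genes (7 of 20). They were -0.12 for 4 liver genes, -0.73 for 3 skin genes and 0.34 for 4 kidney tubule genes, with 0, 0 and 1 called lower. The other 16 of the 27 fixed lists were not called (camera adjusted p from 0.0901 to 0.982), among them TGF-beta signalling and YAP/TAZ targets. By fry, 4 lists called by camera did not pass: NF-kB targets (fry adjusted p = 0.0599), DNA replication (0.115), collagens (0.206) and neuronal genes (0.0887).

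**Figure D3:**
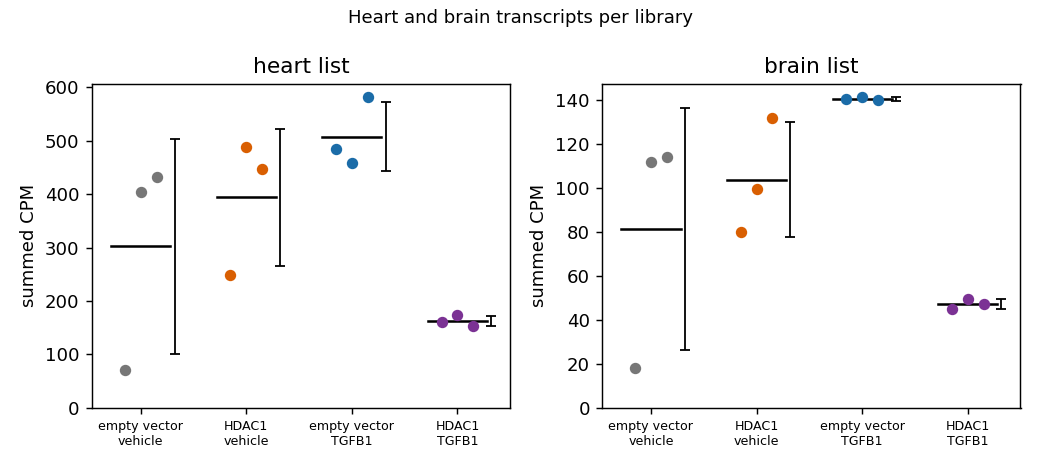
Summed CPM of 21 heart and 20 brain genes per library, with points for libraries, a line at the mean of the 3 libraries of each group and bars of 1 SD. The heart sum was 70.9 CPM in replicate 1 of the empty vector vehicle group and 153.6 to 173.2 CPM with HDAC1 and TGFB1.

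With TGFB1, edgeR called 954 genes, 317 higher and 637 lower with HDAC1, and 225 changed by at least 2-fold (27 higher and 198 lower). The excess of falls was not stable: the DESeq2 test called 610 higher and 682 lower, and without empty vector TGFB1 replicate 2 edgeR called 591 higher and 645 lower. Of the 198, 150 were low in replicate 1 of the empty vector vehicle group, and outside the genes low in that replicate there were 797 calls (311 higher and 486 lower). Of the 10 largest falls taken by the rule for named genes, some were low in that replicate, among them Fabp3 (-1.46) and Des (-1.33), which were not called with the covariate (-0.61 and -0.53). Those that were called in every fit without 1 library and with the covariate were Mybphl, from 1.46 ± 0.319 to 0.179 ± 0.0147 CPM, Zbp1 (-1.41), the endopeptidase Phex (-1.23) and Gpm6a (-1.23). The count of calls was 405 and 495 without empty vector TGFB1 replicates 1 and 3, 237 and 291 without HDAC1 TGFB1 replicates 1 and 3, and 110 with a covariate for heart and brain transcripts. With the covariate the median size of the fold change of the 954 genes went from 0.448 to 0.415 and the median SE from 0.0988 to 0.133. In both treatments 160 genes were called higher with HDAC1 and 288 lower, where independent lists would share 21.0 and 46.6, and 5 were called in opposite directions. Of the 2038 genes called in vehicle, 89.11% had an HDAC1 effect of the same sign with TGFB1. Across all 14601 genes, called or not, which are not independent replicates, the 2 HDAC1 effects were only weakly related (r = 0.116 and rho = 0.310). That correlation also covers genes such as the neuronal list, with medians of 0.27 in vehicle and -1.46 with TGFB1.

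TGFB1 was then compared with vehicle in cells with the empty vector, to describe the response of control cells. Most of the fibrosis genes of the fixed rule rose. Acta2 went from 3.68 ± 0.351 to 21.4 ± 3.67 CPM (log2 fold change 2.55), Ccn2 from 288 ± 47.8 to 1150 ± 147 CPM (2.00) and Col3a1 from 264 ± 32.9 to 825 ± 190 CPM (1.65), with Fn1 (fibronectin) at 0.74 and Tgfb1 at 0.82. Col1a1 was already at 5200 ± 502 CPM and was not called (0.14, edgeR adjusted p = 0.424). The largest rises were in Srpx2 (5.87), the transglutaminase F13a1 (5.72), the laminin chain Lamb3, from 11.5 ± 0.957 to 346 ± 6.48 CPM, Lmcd1 (4.59) and the anchoring collagen Col7a1 (4.38). Apart from Lamb3 these genes started near the floor, so the sizes of their rises are uncertain. In the empty vector vehicle group F13a1 was at 0.044 to 0.215 CPM, Col7a1 at 0.159 to 0.574 CPM and Lmcd1 at 0.442 to 1.007 CPM. Srpx2 was at 0.133 CPM in replicate 1 and 0.524 CPM on average in replicates 2 and 3. Hdac1 itself rose by 0.35 (edgeR adjusted p = 0.00123) and Hdac2 by 0.67.

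By lists, the TGF-beta signalling genes split into 17 up and 3 down of 29, the same when adjusted over the list alone, with Pmepa1 at 1.94 and Inhba, which encodes an activin subunit, from 63.7 ± 1.96 to 180 ± 20.1 CPM (camera adjusted p = 0.00125, and adjusted p = 0.527 with an estimated correlation). Contractile genes were up in 13 and down in 4 of 22 cases, also when adjusted over the list alone, with Tpm1 at 0.90 and Myh11, a smooth muscle myosin, at -1.99 (camera adjusted p = 0.0196, and adjusted p = 0.523 with an estimated correlation). Cell cycle genes rose, with 30 of 30 mitosis genes (median 0.61) and 29 of 30 replication genes (median 0.63), counts that did not move when adjusted over the list alone. Both had camera adjusted p = 4.35e-12, and adjusted p = 0.523 and 0.479 with an estimated correlation. Cholesterol synthesis genes rose in 19 of 24 cases, the same when adjusted over the list alone, with Msmo1 from 160 ± 3.31 to 453 ± 29.0 CPM (camera adjusted p = 7.42e-06, and adjusted p = 0.610 with an estimated correlation).

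Interferon-stimulated genes fell with TGFB1 in 35 of 37 cases, also when adjusted over the list alone. Cxcl10, a chemokine induced by interferon, went from 1584 ± 128 to 302 ± 21.9 CPM, Gbp5 fell by 1.99 and Rsad2 fell by 1.66 on the log2 scale, and the median was -0.62 (camera adjusted p = 5.87e-13, and adjusted p = 0.523 with an estimated correlation). NF-kB targets fell in 15 and rose in 6 of 28 cases (16 and 6 when adjusted over the list alone), with the adhesion molecules Vcam1 at -1.44 and Icam1 at -1.21 (camera adjusted p = 0.0134, and adjusted p = 0.610 with an estimated correlation). Among the 10 largest falls with TGFB1 were Selenbp1 (-3.99), Barx2 (-3.34), Acod1, which makes itaconate (-3.13), and the aldehyde dehydrogenase Aldh3a1, from 506 ± 19.2 to 68.6 ± 7.27 CPM.

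edgeR called 7429 genes, 3780 higher and 3649 lower, and 1441 changed by at least 2-fold (608 higher and 833 lower). The calls of 3 further lists ended without 1 library: HDAC1 complex subunits (13 up and 3 down of 25, 14 and 3 when adjusted over the list alone, median 0.21) without empty vector vehicle replicate 2 (0.20) or empty vector TGFB1 replicate 1 (0.17), ribosomal proteins (15 up of 29 by either adjustment, including when adjusted over the list alone, 0.20) without empty vector TGFB1 replicate 3 (0.08), and matrix glycoproteins (14 up and 4 down of 27, also when adjusted over the list alone, 0.18) without empty vector vehicle replicate 3 (0.16) or empty vector TGFB1 replicate 1 (0.10). Their camera adjusted p was 0.0397, 0.00427 and 0.0446, against adjusted p = 0.631, 0.757 and 0.634 with an estimated correlation. The other 17 lists were not called (camera adjusted p from 0.1004 to 0.917), among them collagens (10 up and 6 down of 19, 11 and 6 when adjusted over the list alone) and collagen processing (5 up and 9 down of 20, also when adjusted over the list alone). By fry, ribosomal proteins did not pass (fry adjusted p = 0.0622).

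The same comparison in cells with HDAC1 gave 7170 calls, 3638 higher and 3532 lower, with 1464 of at least 2-fold (461 higher and 1003 lower). Acta2 rose from 3.05 ± 0.192 to 16.0 ± 0.785 CPM (log2 fold change 2.39), Ccn2 by 1.90, Col3a1 by 1.51, Fn1 by 0.94 and Tgfb1 by 0.70. Col1a1 had a log2 fold change of 0.29 (edgeR adjusted p = 0.0993), and it was called without HDAC1 vehicle replicate 2 (0.38) or HDAC1 TGFB1 replicate 1 (0.37). Cdkn1a fell by 0.18 (edgeR adjusted p = 0.0232), a call that ended without replicate 1 of HDAC1 vehicle (-0.16) or of HDAC1 TGFB1 (-0.18). Pappa, a protease that cleaves binding proteins of insulin-like growth factor, rose by 5.34 and Lefty1, a TGF-beta family antagonist, by 3.78, while Mybphl fell by 4.84 and Aqp1 fell by 3.13. Interferon-stimulated genes fell in 33 of 37 cases (34 when adjusted over the list alone), mitosis genes rose in 22 and fell in 1 of 30 (23 and 1 when adjusted over the list alone, median 0.26), and replication genes rose in 27 of 30, also when adjusted over the list alone (0.36). The camera adjusted p for these was 9.35e-13, 0.000106 and 2.54e-07, against adjusted p = 0.523, 0.610 and 0.527 with an estimated correlation. Glycolysis genes fell in 12 and rose in 2 of 19 cases by either adjustment, including when adjusted over the list alone, with the phosphofructokinase Pfkp at -0.83 and the hexokinase Hk1 at -0.64 (camera adjusted p = 0.00362, and adjusted p = 0.527 with an estimated correlation).

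TGF-beta signalling genes in HDAC1 cells were up in 17 and down in 6 of 29 cases, also when adjusted over the list alone, with Inhba at 2.09 and Tgfb3 at 1.45. Matrix glycoproteins were up in 13 and down in 7 of 27 (14 and 7 when adjusted over the list alone), with Nid1, a basement membrane linker, at 1.25, and NF-kB targets were up in 5 and down in 16 of 28 (6 and 17 when adjusted over the list alone), with Vcam1 at -1.77. Cholesterol synthesis genes rose in 17 and fell in 1 of 24 cases, also when adjusted over the list alone, and ribosomal proteins rose in 13 of 29 (12 when adjusted over the list alone). The camera adjusted p for these lists was 0.000113, 0.0166, 0.0169, 0.00144 and 0.00286, against adjusted p = 0.523, 0.610, 0.610, 0.712 and 0.757 with an estimated correlation. The neuronal list fell (9 of 25 genes, 5 when adjusted over the list alone, median -1.06, camera adjusted p = 0.0166 and adjusted p = 0.757 with an estimated correlation), and 20 of its 25 genes were low in replicate 1 of the empty vector vehicle group. The other 15 lists were not called (camera adjusted p from 0.0830 to 0.911), among them contractile genes (12 up and 7 down of 22, also when adjusted over the list alone). By fry, ribosomal proteins (fry adjusted p = 0.0693), neuronal genes (0.107) and the mitochondrial genome list (0.0622) did not pass.

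Of the calls for TGFB1, 2954 were higher and 2741 lower in both vector groups, where independent lists would share 941.8 and 882.7, and 43 went in opposite directions. Across the 14601 genes, which are not independent replicates, the fold changes of TGFB1 in the 2 vector groups had r = 0.728 and rho = 0.698. In the HDAC1 group the call of the mitochondrial genome list (7 of 13 up, also when adjusted over the list alone, median 0.25) ended without HDAC1 vehicle replicate 2 (0.15) or 3 (0.26) or HDAC1 TGFB1 replicate 1 (0.15), and that of HDAC1 complex subunits (13 up and 2 down of 25 by either adjustment, including when adjusted over the list alone, 0.16) without HDAC1 vehicle replicate 1 (0.20) or HDAC1 TGFB1 replicate 2 (0.14). Their camera adjusted p was 0.0362 and 0.0320, against adjusted p = 0.747 and 0.610 with an estimated correlation.

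**Figure D4:**
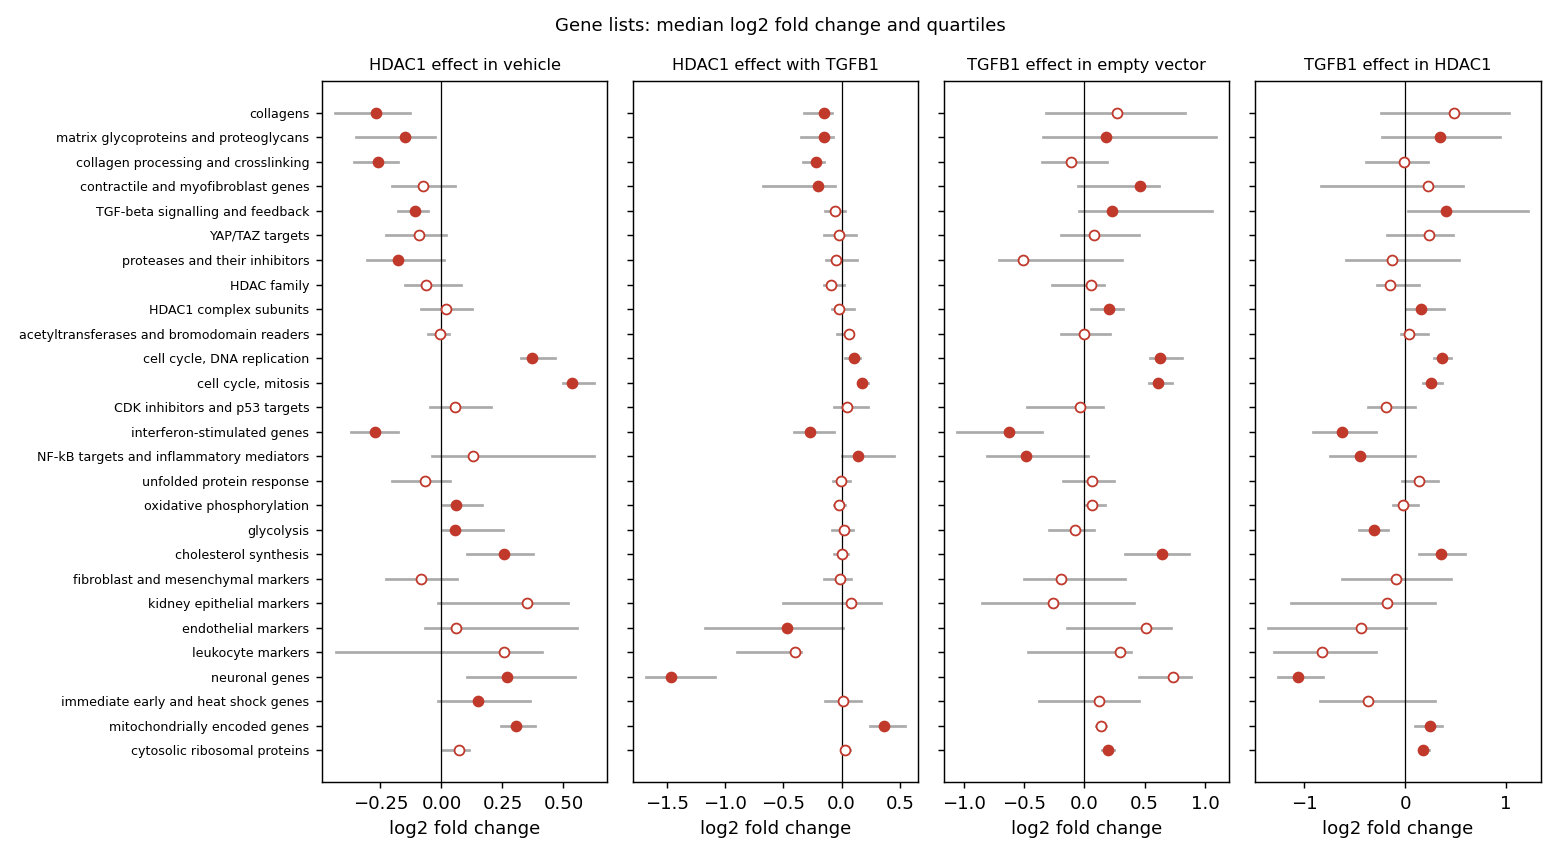
Median log2 fold change of the 27 gene lists in 4 comparisons, with grey lines from the lower to the upper quartile and filled points where the camera test with a preset correlation passed. The mitosis list had medians of 0.54 and 0.18 for HDAC1 and 0.61 and 0.26 for TGFB1.

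Whether the effect of HDAC1 differed between the treatments was tested as the interaction. Cell division genes had the smallest p of all lists: 8 of 30 mitosis genes and 2 of 30 replication genes had a lower HDAC1 effect with TGFB1 than in vehicle (27 and 16 when adjusted over the list alone). Kif20a rose with HDAC1 from 85.4 to 143 CPM in vehicle and was at 134 ± 6.12 and 151 ± 4.13 CPM with TGFB1, a difference of -0.56 on the log2 scale. The median difference was -0.37 for mitosis and -0.27 for replication (camera adjusted p = 2.71e-21 and 1.78e-13, and adjusted p = 0.294 and 0.403 with an estimated correlation). Aspn, a small matrix proteoglycan, was at 75.1 ± 11.9 and 35.1 ± 5.43 CPM in vehicle and at 68.5 ± 3.45 and 64.3 ± 5.08 CPM with TGFB1, a difference of 1.00. Both calls ended without HDAC1 TGFB1 replicate 1 (-0.55 for Kif20a and 0.93 for Aspn) or 3 (-0.57 and 1.04). None of the 8 genes of fibrosis, TGF-beta signalling and cell cycle arrest was called, and the differences were -0.16 for Acta2, 0.15 for Col1a1 and -0.09 for Ccn2 (edgeR adjusted p = 0.783, 0.806 and 0.849).

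edgeR called 70 genes for the interaction, 20 higher and 50 lower, and 1887 had an unadjusted p under 0.05. This count rested on single libraries: in vehicle it was 14 and 257 without empty vector replicates 2 and 3 and 28 and 8 without HDAC1 replicates 1 and 3, and with TGFB1 it was 32 without empty vector replicate 1 and 5, 26 and 3 without HDAC1 replicates 1, 2 and 3. With a covariate for heart and brain transcripts it was 0 (850 at an unadjusted p under 0.05), although the differences of the 70 genes stayed about as large. Their median size went from 0.589 to 0.552, 100% kept their sign and the median SE rose from 0.117 to 0.164. The DESeq2 test gave 242.

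Further lists that passed for the interaction were cholesterol synthesis (median -0.24, camera adjusted p = 1.14e-05, and adjusted p = 0.610 with an estimated correlation) and proteases and their inhibitors (0.16, camera adjusted p = 0.000209, and adjusted p = 0.294 with an estimated correlation), with 0 genes called in either over all genes and 4 lower and 5 higher when adjusted over the list alone. The neuronal (-1.80) and endothelial (-0.46) lists also passed (camera adjusted p = 1.27e-10 and 0.00144, and adjusted p = 0.527 and 0.294 with an estimated correlation). The calls of 5 lists with small medians ended without single libraries, and these lists had adjusted p from 0.527 to 0.757 with an estimated correlation. TGF-beta signalling (0.10) was not called without empty vector vehicle replicate 1 (0.09), HDAC1 vehicle replicate 2 (0.11), empty vector TGFB1 replicate 2 (0.10) or HDAC1 TGFB1 replicates 2 (0.07) and 3 (0.08). The unfolded protein response (0.11) was not called without empty vector TGFB1 replicates 1 (0.09) or 2 (0.09), and glycolysis (-0.13) without empty vector vehicle replicate 2 (-0.07). Oxidative phosphorylation (-0.06) was not called without empty vector vehicle replicate 1 (-0.06), HDAC1 vehicle replicates 1 (-0.06) and 2 (-0.07) or empty vector TGFB1 replicate 3 (-0.02). Kidney epithelial genes (-0.20) were not called without replicate 2 of either vehicle group (-0.20 for empty vector and -0.24 for HDAC1), empty vector TGFB1 replicates 1 (-0.32) and 2 (-0.04) or HDAC1 TGFB1 replicate 1 (-0.25). By fry, these 5 lists (fry adjusted p from 0.0599 to 0.429), cholesterol synthesis (0.207) and neuronal genes (0.0672) did not pass. The other 16 lists were not called (camera adjusted p from 0.106 to 0.911).

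Last, the genes moved by HDAC1 on average were compared with those moved by TGFB1 on average. HDAC1 had 2947 calls (1389 higher and 1558 lower) and TGFB1 8887 (4517 higher and 4370 lower). Of these, 1027 were higher with both and 1035 lower with both, where independent lists would share 429.7 and 466.3. Another 133 were higher with HDAC1 and lower with TGFB1, and 224 the reverse, against 415.7 and 482 for independent lists. Across genes the fold changes had r = 0.309 and rho = 0.394, with a covariance of 0.0656. In 20 simulations with no effects the mean r was 0.0263, the mean rho 0.0167 and the mean covariance 0.000655. These simulations held no shift shared by the libraries of a group. A shift confined to the HDAC1 with TGFB1 group, or to the empty vector vehicle group, enters both average effects with the same sign. The simulations therefore cannot show whether the relation goes beyond such a shift. With the covariate for heart and brain transcripts the r was 0.3449. The r was 0.0521 without a filter on low counts and 0.0220 with DESeq2 fold changes, and 0.3045 with those fold changes over the genes tested here.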

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

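The results in this part were picked out because the HDAC1 effect differed between vehicle and TGFB1 in the interaction test. The interaction test and the exchange of labels were planned, but the covariate for heart and brain transcripts and the test of an earlier rise by TGFB1 were chosen after the result was seen.

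The count of 70 genes called for the interaction is small beside the counts for either treatment alone. Exchanging the group labels gave as many calls in 7 of 100 splits, the real split included. The highest other split gave 2947 calls, and it exchanges the labels within 1 treatment, which turns the average effect of HDAC1 into a difference. The highest of the rest gave 437. Labels were exchanged inside each treatment, so any split that is uneven between the treatments carries part of that average effect into the difference. The 7 of 100 is therefore not a rate of chance for the interaction, and chance cannot be excluded. None of the 20 named genes called for the interaction was called in all fits without 1 library.

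Among the largest differences, Mybphl (-1.80), the water channel Aqp1 (-1.31), Vsnl1 (-1.31), the neurotrophin receptor Ngfr (-1.25) and Dnajc6 (-1.14) were relatively lower with HDAC1 when TGFB1 was present. Ngfr was raised by HDAC1 from 4.72 to 10.9 CPM in vehicle and was at 1.41 and 1.33 CPM with TGFB1. Aqp1 was at 33.8 and 45.0 CPM in vehicle and at 9.62 and 5.04 CPM with TGFB1. In the other direction were the potassium channel Kcnj2 (1.04), Aspn (1.00), Ccn5 (0.77), Inhbb (0.65) and Wnt5a (0.64).

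Genes of the fixed lists that differed were Inhba (0.59) and Tgfb3 (0.38) of TGF-beta signalling, the chemokine Cxcl10 (0.56), and the kinase inhibitor Cdkn1b (0.47), which fell with HDAC1 only in vehicle. Inhba was at 63.7 and 61.4 CPM in vehicle and rose from 180 to 260 CPM with HDAC1 when TGFB1 was present. Cell cycle genes differed the other way: E2f1 (-0.63), Ube2c (-0.59), Cdc20 (-0.58), Kif20a (-0.56), Ccnb1 (-0.49) and Cdc6 (-0.44).

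Of the lists that differed, mitosis (median -0.37), DNA replication (-0.27) and cholesterol synthesis (-0.24) are 3 groups that TGFB1 raised in control cells. Not every list raised there behaved so. TGF-beta signalling was also raised but differed in the other direction. Matrix glycoproteins, contractile genes, HDAC1 complex subunits and ribosomal proteins were raised as well and were not called for the interaction. Of the 11 lists that passed camera with the preset correlation, 0 passed with an estimated correlation. The neuronal (-1.80), endothelial (-0.46) and kidney epithelial (-0.20) lists had low median levels (1.96, 1.43 and 1.68 CPM) but also hold abundant genes such as Krt8, and 20 of the 25 neuronal genes were low in replicate 1 of the empty vector vehicle group. Proteases (0.16), the unfolded protein response (0.11), TGF-beta signalling (0.10), glycolysis (-0.13) and oxidative phosphorylation (-0.064) differed by little.

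The smaller rise of mitosis genes with HDAC1 when TGFB1 was present was weighed against 3 explanations. It is not explained by the odd replicate 1 of the empty vector vehicle group, because the median difference was -0.327 without it. It is not explained by heart and brain transcripts either, because the median was -0.348 with the covariate. It may be that TGFB1 had already raised these genes. The median rise with TGFB1 in control cells exceeded that with HDAC1 in vehicle by 0.0783, which leaves room for such a limit but does not show it. Medians of 30 genes with related regulation were compared. Both rises were also measured from the same empty vector vehicle libraries, which enter the difference too. A low level in that group would by itself enlarge both rises and make the difference negative, so this comparison cannot decide. Measuring division rates or cell numbers in the 4 groups would separate these readings.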

How the results depend on the processing

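Most counts of calls stayed within 1.5-fold under the other fits, and the cause of the changes below was not tested except where stated. The count for HDAC1 in vehicle was 2038, and it ranged from 1144 to 2166 without 1 library, lowest without HDAC1 vehicle replicate 1 and next without empty vector vehicle replicate 1 (1239). With TGFB1 it was 954, and it ranged from 237 to 1236 without 1 library, with 405, 495, 237 and 291 without empty vector replicates 1 and 3 and HDAC1 replicates 1 and 3. The split was 317 higher and 637 lower, against 610 and 682 with the DESeq2 test and 591 and 645 without empty vector TGFB1 replicate 2. The count was 110 with the covariate for heart and brain transcripts. There the median standard error of the 954 genes rose from 0.0988 to 0.133 while the median size of the fold change went from 0.448 to 0.415, and 99.7% kept their sign.

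The interaction was the least stable result: 70 genes became 479 without a filter, 242 with the DESeq2 test, 0 with the covariate and from 3 to 257 without 1 library. With the covariate the median size of these differences went from 0.589 to 0.552 and 100% kept their sign, while the median standard error rose from 0.117 to 0.164. The values were 14 and 257 without empty vector vehicle replicates 2 and 3, 28 and 8 without HDAC1 vehicle replicates 1 and 3, 32 without empty vector TGFB1 replicate 1, and 5, 26 and 3 without HDAC1 TGFB1 replicates 1, 2 and 3. The correlation of the average effects, 0.309, was 0.0521 without a filter and 0.0220 with DESeq2 fold changes, but 0.3045 when these were taken over the genes tested here, which ties that change to genes of low count. Without 1 library it ran from 0.215 to 0.342, with 0.259 and 0.264 without HDAC1 vehicle replicates 2 and 3 and 0.261, 0.215 and 0.271 without empty vector TGFB1 replicates 1, 2 and 3.

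A few small effects changed sign. With HDAC1 and TGFB1, Fn1 ran from -0.14 to 0.11 without 1 library, highest without empty vector TGFB1 replicate 1, and was 0.031 without HDAC1 TGFB1 replicate 1. Cdkn1a ran from -0.055 to 0.026, highest without empty vector TGFB1 replicate 3, and was 0.022 without HDAC1 TGFB1 replicate 1 and 0.0023 with the DESeq2 test. For the interaction, Col3a1 ran from -0.30 to 0.033, highest without HDAC1 vehicle replicate 2, and was 0.00053 without empty vector TGFB1 replicate 1, and Ccn2 ran from -0.20 to 0.038, highest without empty vector vehicle replicate 3. None of these was called in the fits in which the sign changed. The neuronal list ran from -0.16 to 0.64 for HDAC1 in vehicle, lowest without empty vector vehicle replicate 1, and was 0.0045 with HDAC1 and TGFB1 under the covariate, which holds 9 of the genes of that list, so a median near 0 there was partly built in.

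Of 58 list calls over the 5 comparisons, 20 ended with fry and 58 with an estimated correlation, 11 with the covariate besides the neuronal list whose sign changed (5 of these 11 for the interaction), 10 without the genes low in replicate 1 of the empty vector vehicle group and 9 at a mean CPM of at least 1.

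Over all genes the replicate numbers showed no clear pairing. Libraries sharing a number had r from -0.0875 to 0.118 after group means were removed, and 5 of 12 correlated best with their own number. Hdac1l, however, kept its order in both HDAC1 groups. It was at 1297, 851.9 and 1367 CPM in replicates 1, 2 and 3 with vehicle and at 1211, 801.6 and 1257 CPM with TGFB1. A pairing of the HDAC1 libraries by number can therefore not be excluded, and the main fit had no replicate block. With a replicate block the counts were 1790 and 784 for HDAC1, 7197 and 6915 for TGFB1 and 98 for the interaction, and 4 of the 58 list calls ended, 2 of them for the interaction.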

Other observations

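Single deacetylase genes changed with TGFB1 in both vector groups, although the HDAC family was not called as a list (4 up and 4 down of 18 with the empty vector, 3 up and 4 down with HDAC1, camera adjusted p = 0.834 and 0.587). Hdac2, a second class I deacetylase, rose by 0.67 with the empty vector and 0.69 with HDAC1 on the log2 scale, and Kdm1a, the gene of a histone demethylase found in HDAC1 complexes, rose by 0.59 and 0.56. Hdac5, a class II deacetylase, fell by 0.61 and 0.78. Acetyltransferases and bromodomain readers were not called as a list either (camera adjusted p = 0.917 and 0.487).

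The 2 kinds of mitochondrial transcripts moved apart with HDAC1. The share of mitochondrial messenger RNA was 1.81% with the empty vector and 2.23% with HDAC1 in vehicle, and 1.83% and 2.26% with TGFB1. The share of mitochondrial ribosomal RNA went the other way, from 0.105% to 0.0615% in vehicle and from 0.0463% to 0.0236% with TGFB1. Poly(A) selection captures the 2 kinds of RNA differently, and these shares were not tested.

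The tests of the plasmid reads, the neighbouring genes, the heart and brain transcripts and the library sizes were chosen after the result was seen, whereas the exchange of labels was planned.

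Hdac1l was about as high as a strongly expressed gene in all 6 HDAC1 libraries, at 1172 and 1090 CPM on average. It may reflect reads of the human plasmid assigned to the rat copy: over those 6 libraries Hdac1l followed the added Hdac1 signal with r = 0.942 (exact p = 0.0153). This p takes the 6 libraries as independent, although Hdac1l had a similar level at each replicate number in both treatments. If equal numbers are pairs, the p is too small. The rank correlation was weaker (rho = 0.829, exact p = 0.0583), and r was 0.481 without the 2 libraries farthest from the median. Induction of the rat locus together with its neighbours is not supported by the data, because 0 of the 2 neighbouring genes tested were called higher in both comparisons. This rests on Acsl3, named here outside the rule for named genes (log2 fold changes of -0.003 in vehicle and -0.18 with TGFB1). The other, Scg2 (0.26 and -1.70), belongs to the neuronal list, which was low with HDAC1 and TGFB1, so it could hardly have been called higher there. Induction of Hdac1l alone stays possible. Aligning the reads to the human and rat sequences would settle where the Hdac1l signal comes from, and the rise of rat Hdac1 itself may have the same source.

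The 198 genes at least 2-fold lower with HDAC1 and TGFB1 may largely be transcripts that entered some libraries from outside the culture, such as those of heart and brain. Of all genes tested 5.42% were low in replicate 1 of the empty vector vehicle group, against 75.8% of these, a ratio of 14.0. The 198 genes had a median level of only 1.05 CPM, and the share over all genes was not matched for level. Of the 198, 8 were in the heart or brain list. Heart and brain genes moved together across libraries, with summed levels in a ratio of 3.11 to 4.91. Repression by HDAC1 cannot be ruled out, since the median of these genes was -0.731 with the covariate and 11 of them were still called. Smaller libraries in the group are not the reason, because the largest total with HDAC1 and TGFB1 was 1.27 times the smallest with the empty vector and TGFB1.

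Chance was weighed for the counts by exchanging group labels. For the average effect of HDAC1, the real split gave 2947 calls and 1 of 100 splits reached it, the highest other giving 1086. For TGFB1 the real split gave 8887, 1 of 100 reached it and the highest other gave 2858. A random division of independent libraries is therefore unlikely to give either count. Chance differences between cultures or transfections were not tested, since the labels do not say whether replicates are separate cultures. Within single comparisons only 10 splits exist, which is too few: 2038, 954, 7429 and 7170 genes were called with the real labels, 1 of 10 splits reached each, and the highest other gave 0.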
